A study of Homo sapiens with 4 samples.

How the data were processed

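RNA of IGROV1-R10 cells was sequenced from 4 libraries, 1 each for the input and the pull-down of cells given biotin-carrying miR-491-5p or a biotin-carrying control miRNA. Each library held the pooled RNA of 3 experiments and was made with a kit for stranded total RNA, per the labels' protocols. Groups were taken from the sample titles, and each column of the table from its name and title. The values are whole-number read counts per gene, as the authors deposited them, without normalization. Reads were counted with featureCounts 1.5.0-p1 on GENCODE release 24 and hg38, per the file headers. The header's command counts without regard to strand and leaves out reads marked as duplicates and reads that fit several places. It also asks for both mates to map, while reads are counted singly. Reads that overlap several genes are left out, so overlapping and antisense genes, and near-identical copies, have uncertain values. The submitters' processing notes also name STAR, DESeq2 1.10.1 and GRCh38.

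Counts were normalised here with DESeq2 1.42.0 size factors over the 4 libraries (0.957, 1.24, 0.778 and 1.13 for the miR-491-5p input, its pull-down, the control input and its pull-down). The total counts were 59588552, 61705443, 47679684 and 62582646. Log2 ratios were taken on normalised counts plus 1, for the enrichment defined in the design text, for each part of it and for pull-down over input within each transfection. The standard error of each ratio is the counting error of its libraries, with 0.5 added to each count, and the interval is 1.96 standard errors on each side. Genes entered with a mean normalised count of at least 50, which kept 12662 of 60554 genes and 99.7% of the counts. No test across genes was planned, since each group has 1 library. Pull-down and input of a transfection come from the same lysate, so pull-down against input was later also tested with edgeR, with the transfection as a block. The rule for the genes named in the text, the comparisons, the samples and the alternatives not said to be added were fixed before the data were examined. The tests of the closing section were written afterwards, for patterns already seen. For the enrichment the rule took the 12 highest and 6 lowest genes and the 8 highest lncRNA genes, for the inputs the 8 highest and 8 lowest, and for the beads the 6 highest and 6 lowest by the mean of both transfections, each with an interval that excluded 0. It also took BCL2L1, EGFR, MIR491 and FOCAD, and the 3 largest absolute values of each fixed list whose median lay outside the central 95% of random lists, of which the text gives a part. The remaining listed targets, and the genes said to be so in the closing section, were chosen after their values were seen.

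Gene names were not part of the table. They came from the positions of RefSeq genes on GRCh38.p14, the same build, in 4 stages: both ends within 20 bp; then the best overlap on both sides, of at least 0.4 of the joint span and 0.2 above the next, with an end within 2000 bp; then an end within 20 bp of a protein-coding gene; then the same for any other named gene with an overlap of at least 0.1. RefSeq genes under 300 bp were matched only at both ends. This named 11661 of the 12662 genes, which held 96.9% of their counts. With the RefSeq positions moved by 3 Mb, 1004 genes still matched, against 41082 in place. The rule was settled after the counts had been looked at. Several versions were tried, 1 earlier version gave visibly wrong names, and the limits were loosened partly so that TNRC6A, already seen to be high on the beads, would be named. A stricter rule with an overlap of 0.5 and an end within 1000 bp, without the last stages, named 11074 genes and left TNRC6A, BCL2L1-AS1, H2BC7, TRIB3, ISG15 and FGD5-AS1 unnamed, and also BCL2L2 and APOH, on which a list median and the hepatocyte share rest in part, and none of the genes named by both rules changed its name. The MIR491 hairpin missed the rule and was taken by its position.

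There were 27 gene lists, fixed before the data were examined, 8 of them by a pattern of gene symbols. After the files had been seen, the patterns of the mitochondrial lists were changed to the RefSeq spelling and the pattern lists were restricted to protein-coding genes, or to rRNA genes for the mitochondrial rRNAs. No immune marker gene and only 2 mitochondrial rRNA genes were measured, so those lists have no percentile. Each list's median was set among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. The targets reported elsewhere were listed from background knowledge.

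The calculations were tested on simulated counts for the enrichment of 12663 genes, with 200 genes changed, of which 199 passed the count minimum. Of the genes changed by 4-fold, 100.0% were called at 1.5-fold with an interval excluding 0, and of those changed by 2-fold, 97.1%. Of 12464 unchanged genes 0.064% were called at 2-fold. The intervals held the true value for 94.7% of the unchanged genes. Of 100 random lists without a change, 6 lay outside the central 95%. These simulations hold counting error only.

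The alternatives were total counts, TMM (edgeR 4.0.16), other count minimums, other pseudocounts and other fold limits, and for the enrichment separate size factors, the pull-downs alone and protein-coding genes only. Alternatives added after the data were seen were a minimum on the pull-downs, leaving out hepatocyte and fibroblast genes, the stricter name match and the edgeR test. Sequences of 3′ untranslated regions were not used here, so the planned comparison of transcripts with seed sites was not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.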

Results

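RNAs purified together with transfected miR-491-5p were measured in IGROV1-R10, a human ovarian cancer line. The cells were transfected at 60 nM with miR-491-5p carrying biotin, or with a biotin-carrying worm miRNA (a cel-miR, named cel-miR-65 in the design text) as the control. After the nuclei had been removed, 10% of each lysate was kept as the input and the rest was held on streptavidin beads for 4 h and washed 5 times (the pull-down). There were 4 groups, namely input and pull-down for each miRNA, with 1 library in each group, made from the pooled RNA of 3 experiments. The gene counts summed to 59588552 in the miR-491-5p input, 61705443 in the miR-491-5p pull-down, 47679684 in the control input and 62582646 in the control pull-down. With 1 library per group, no difference between the miRNAs has a replicate check and no p-value is given for one. The intervals are 95% counting intervals. They cover counting error only, as each group has 1 library. Reads without molecular identifiers are not independent molecules, so the intervals can understate even that error. All log2 values are on normalised counts plus 1. A gene was counted as higher or lower when it differed by at least 2-fold and its interval excluded 0, among 12662 genes with a mean normalised count of at least 50.

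The first question, from the design text, was which transcripts were enriched with miR-491-5p: the pull-down ratio (miR-491-5p over control) divided by the input ratio. BCL2L1, which encodes the anti-apoptotic protein BCL-xL (chromosome 20, 31664452 to 31723989), was enriched 2.42-fold, with a log2 value of 1.27 and an interval of 1.20 to 1.35. Its normalised count was 7706 in the miR-491-5p pull-down against 4600 in the control pull-down, and 4385 in the miR-491-5p input against 6332 in the control input. EGFR, the epidermal growth factor receptor (chromosome 7, 55019021 to 55256620), had an enrichment of 0.43 (0.38 to 0.49). In the pull-downs alone EGFR was lower with miR-491-5p, at -0.62, and its enrichment was above 0 because its input ratio was lower still, at -1.05. FOCAD, the host gene of the miR-491 hairpin, had an enrichment of 0.13. The MIR491 locus itself (chromosome 9, 20716100 to 20716209) held 6, 24, 5 and 10 counts in the miR-491-5p input, its pull-down, the control input and its pull-down, and its enrichment of 1.08 had an interval from -0.87 to 3.02.

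Among 17 genes fixed beforehand as targets reported elsewhere, 13 were measured, and 11 of them had an enrichment above 0. Their median enrichment was 0.56, at percentile 99.96 of 10000 random lists matched on expression, whose central 95% ran from -0.36 to 0.32. FOXP4, a forkhead transcription factor, had the largest value, 2.13, with a counting standard error of 0.19. FGFR4, a fibroblast growth factor receptor, followed at 1.54 (1.27 to 1.81), and GIT1, a GTPase-activating scaffold protein, at 1.37 (1.25 to 1.49). With BCL2L1 these were the 4 listed genes past 2-fold. SMAD3 at -0.28 and CDK6 at -0.47 lay below 0. In the input all 13 had a ratio below 0, and the interval excluded 0 for 11 of them. In the pull-downs 8 were above 0 and 5 below.

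**Figure D1:**
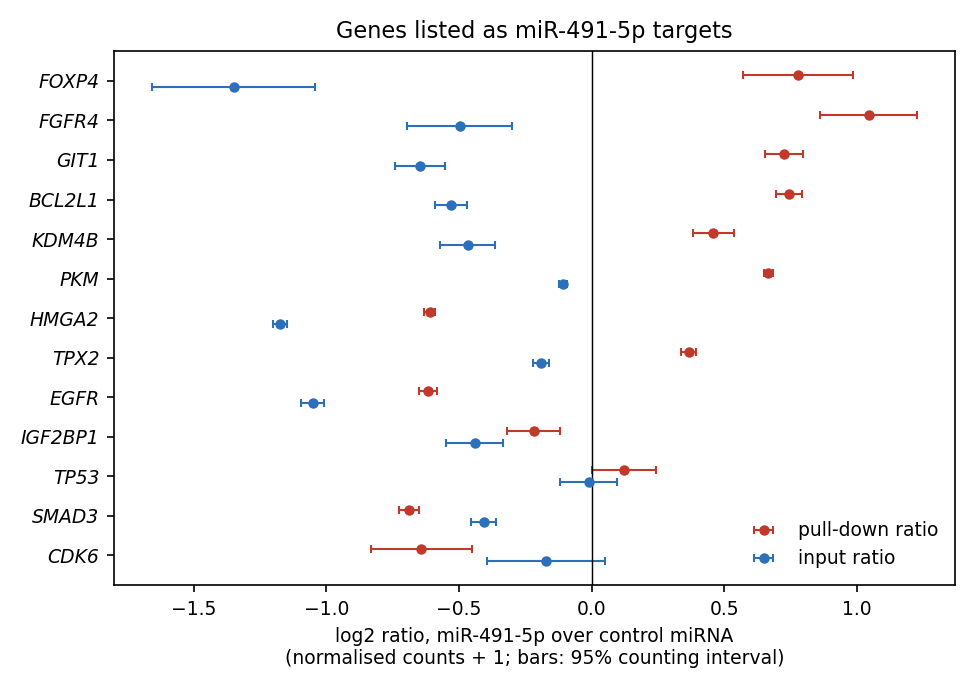
Log2 ratio of miR-491-5p over control miRNA in the pull-downs (red) and in the inputs (blue) for the 13 measured genes listed as targets, with 1 library per group and bars for the 95% counting interval. All 13 input ratios lie below 0, while the pull-down ratio lies above 0 for 8 genes and below 0 for HMGA2, EGFR, IGF2BP1, SMAD3 and CDK6.

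Over all genes, 565 were enriched and 673 were depleted. Scaling by total counts moved the median of all genes by 0.18 and gave 888 enriched and 445 depleted, so that the share of enriched genes among the calls went from 45.6% to 66.6%. Of the 565 enriched genes, 252 were also at least 2-fold higher in the pull-down comparison alone. Of the 673 depleted genes, 324 were also lower there.

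The 7 highest enrichment values belonged to genes of secreted liver proteins, namely HP (haptoglobin), FGB, FGA and FGG, which encode the fibrinogen chains, ORM1, APOB and ALB (serum albumin). These values came from the inputs. HP, FGB, FGA and ORM1 had 0 counts in the miR-491-5p input, so their sizes are set by the pseudocount: HP had 10.15 (5.68 to 14.62) with a pseudocount of 1 and 7.09 with 5, and FGA 8.10 (1.17 to 15.03) and 5.80. APOB had 7.58 (5.43 to 9.73). ALB had 1298 counts in the control input against 5, 0 and 2 in the miR-491-5p input, its pull-down and the control pull-down, and FGA had 213 in the control input and 0 in the other libraries. C3, a complement protein gene, was enriched by 3.13 (2.67 to 3.59) with an input ratio of -2.65 and a pull-down ratio of 0.49. The other 4 of the 12 highest were also higher in the miR-491-5p pull-down than in the control pull-down. TERT, the catalytic subunit of telomerase, had an enrichment of 3.31 (2.36 to 4.26) and a pull-down ratio of 2.09. The pseudogene GPX1P1 had an enrichment of 3.60 and a pull-down ratio of 2.51, and it can share reads with GPX1, so its value is uncertain. ENSG00000227063 and ENSG00000261069, which matched no named gene, had pull-down ratios of 3.48 and 3.35. In pull-down over input, ENSG00000227063 had -0.50 (-0.74 to -0.27) with miR-491-5p and -4.19 with the control. Its value thus came from low counts on the control beads, while ENSG00000261069 had 4.09 with miR-491-5p and 0.45 with the control.

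Among the lncRNA genes, ZFAND2A-DT was highest, with an enrichment of 2.46 (1.99 to 2.93) and normalised counts of 873 and 184 in the miR-491-5p and control pull-downs. It was followed by MPDU1-AS1 at 1.63, BCL2L1-AS1 at 1.56, CASC8 at 1.55, ATP6AP1-DT at 1.44, LINC00239 at 1.42, LOC101929767 at 1.41 and POLR2J3-UPK3BL2 at 1.40. Strand was not used in the counting, so reads of BCL2L1-AS1 and BCL2L1, which overlap, cannot be told apart, and the same holds for MPDU1-AS1. The name of BCL2L1-AS1 rests on the loosest stage of the match of positions. The pull-down ratio of POLR2J3-UPK3BL2 was -0.06, so its enrichment came from the inputs. For miR-491-5p pull-down over input, CASC8 had -0.53, ATP6AP1-DT -0.63 and LINC00239 -0.49 (-1.02 to 0.04), so none of them stood above its input on those beads. On the control beads they were lower still, at -2.1, -2.1 and -1.9.

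Among the most depleted genes, H2AC12, SOCS6, JUND, PIAS3 and GLYR1 were higher on the control beads than in the control input. H2AC12, a histone H2A gene, had an enrichment of -5.13 (-5.24 to -5.01), with 39472 normalised counts in the control pull-down and 1223 in the miR-491-5p pull-down. SOCS6, a suppressor of cytokine signalling, had -5.09 (-5.17 to -5.00), with 90964 against 5277. JUND, an AP-1 transcription factor, had -3.81, PIAS3, an inhibitor of STAT3, -3.49, and GLYR1 -3.48. A short locus on chromosome 6 (27631409 to 27631532), ENSG00000238648, had -4.62, with a log2 pull-down over input of -3.79 for miR-491-5p and 0.83 for the control. Its position fits a tRNA gene and its name is uncertain. Histone genes have near-identical copies, so the value of H2AC12 is uncertain.

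In the pull-downs alone, 316 genes were higher with miR-491-5p and 402 were lower. Under total counts these became 522 and 263, which moved the share of higher calls from 44.0% to 66.5%. Among the listed targets the largest absolute pull-down ratios were those of FGFR4 at 1.04, FOXP4 at 0.78 and BCL2L1 at 0.74, and the median of the 13 was 0.37, at percentile 99.67. Among the anti-apoptotic BCL-2 genes, BCL2 had a pull-down ratio of -1.51 and MCL1 of -1.03, while BCL2L1 lay above 0. The median of the 4 measured members was -0.61, at percentile 1.65. BCL2L2, one of the 4, is named by a looser match of positions, and without it the median was -1.03, at percentile 0.43. The input ratio of BCL2 was also below 0, at -0.91, so its enrichment was -0.60 (-1.27 to 0.08), and the median enrichment of the 4 was -0.54, inside the random lists.

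In the inputs, which give RNA levels after transfection, 92 genes were higher with miR-491-5p and 65 were lower, and 98.8% of genes differed by less than 2-fold. The 8 lowest were the 7 plasma protein genes and C3. Where the miR-491-5p input held 0 counts, the control input was at least 110.7-fold higher for HP, 87.3-fold for FGA and 71.3-fold for FGB, taking 3 counts as the floor of that library. Of 17 measured collagen genes, COL1A1 at -2.54 and COL1A2 at -1.69 were lower and 15 did not pass, among them COL3A1 at -0.97, with a median of -0.24. The highest were EVI2A at 2.20, ENSG00000254428 at 1.98, GCSAM at 1.92, ENSG00000279080 at 1.89, PGGHG at 1.67, ENSG00000258891 at 1.66, ACVR1C at 1.65 and SCARNA1 at 1.61. EVI2A had a normalised count of 5.1 in the control input and 27.2 in the miR-491-5p input.

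Among the listed targets the lowest input ratios were those of FOXP4 at -1.35, HMGA2, a chromatin protein of embryonic and tumour cells, at -1.17, and EGFR at -1.05. The median of the 13 was -0.47, at percentile 0.00 of the random lists. The endoplasmic reticulum stress genes had a median of -0.19, at percentile 0.04, and 15 of 18 were below 0. ATF3 had -0.68, CHAC1 -0.57 and TRIB3 -0.48, and none of the 18 passed 2-fold. The EGFR, RAS and PI3K list had a median of -0.09, at percentile 1.12, with SPRY4 at -0.75 and MTOR at -0.65.

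**Figure D2:**
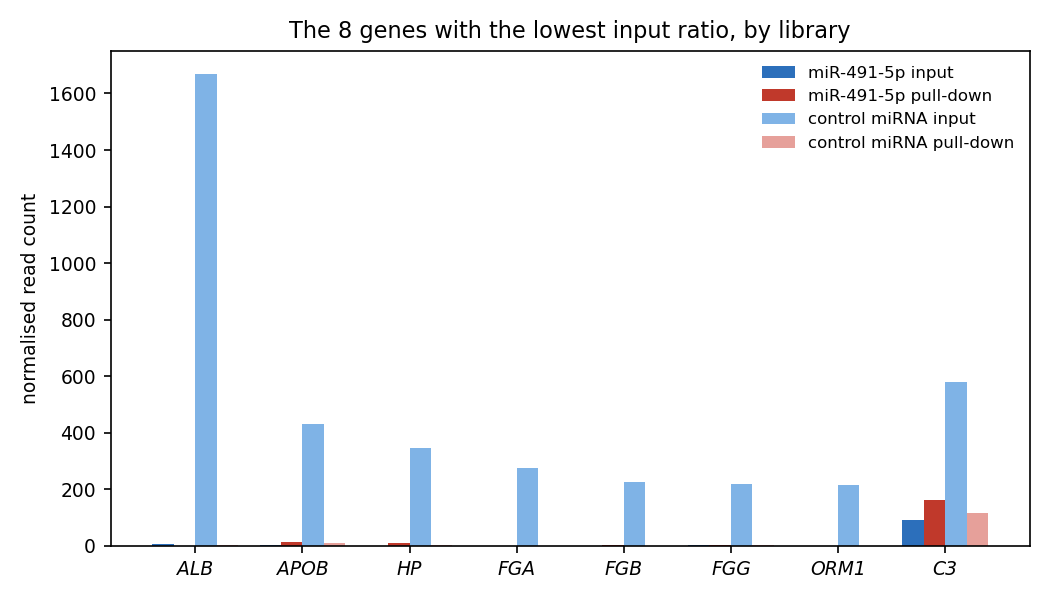
Normalised read counts in each of the 4 libraries for the 8 genes with the lowest input ratio, with 1 library per bar. The control input stands above the other 3 libraries for each gene, with 1668 for ALB and 581 for C3.

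Pull-down over input was then compared within each transfection, to show which RNAs the beads held with either miRNA. ACACA, which encodes acetyl-CoA carboxylase, was the highest by the mean of both, with 3.70 for miR-491-5p and 4.81 for the control. TNRC6B, which encodes a partner of Argonaute in miRNA silencing, had 2.10 and 4.21. LRRN3 had 3.46 and 3.05, the small nucleolar RNA SNORA73B 3.28 and 2.94, EVI2A 1.91 and 4.21, and ENSG00000278896 3.32 and 3.69. In the miR-491-5p and control inputs LRRN3 had only 18 and 16 counts, EVI2A 26 and 4, and ENSG00000278896 15 and 6. The lowest were COL3A1 at -4.87 and -5.74, COL1A2 at -3.75 and -4.47, and the signal recognition particle RNAs RN7SL2 at -2.69 and -3.36 and RN7SL3 at -2.64 and -2.74, whose near-identical copies make the values uncertain. ENSG00000260035 and ENSG00000263740 completed the 6 lowest.

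With miR-491-5p 676 genes were higher and 628 lower on the beads, and with the control miRNA 1090 and 1268. In both, 337 were higher and 360 lower, against 58.2 and 62.9 for independent lists of those sizes. An edgeR test added after the data were seen, with the transfection as a block, gave 540 genes higher and 662 lower (at least 2-fold, FDR under 0.05), including 331 of the 337 and all 360. It has 1 residual degree of freedom, and its 2 pairs had different miRNAs. The test used the same 4 libraries, and genes past 2-fold in both pairs agree between its blocks. The overlap is thus no separate check of the calls. Under total counts the shared calls were 577 and 78, which moved the share of higher calls from 48.4% to 88.1%, and the medians of all genes moved by 0.32 and 0.14. Across genes, which are not independent replicates, the log2 values correlated with r = 0.60 and rho = 0.62, and the 2 ratios have no library in common.

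**Figure D3:**
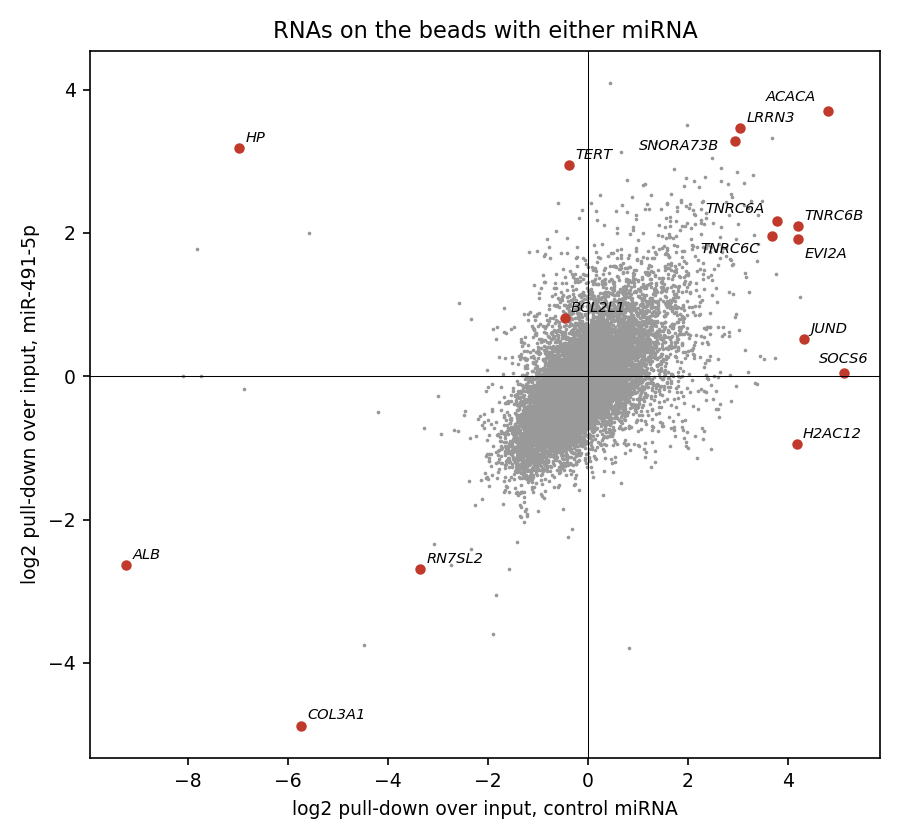
Log2 pull-down over input with the control miRNA (x axis) and with miR-491-5p (y axis), 1 point per gene and 1 library per group, with named genes in red. ACACA lies at 4.81 and 3.70, while SOCS6 lies at 5.13 with the control and 0.04 with miR-491-5p.

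Of the fixed gene lists, 25 had at least 3 measured genes, and the median enrichment of 12 lay outside the central 95% of random lists. For lists of independent genes 1.25 would, but the random lists take the members as independent and were not matched on exon length. Of the same lists, 12 lay outside in the pull-downs, 10 in the inputs, and 12 and 9 on the miR-491-5p and control beads. The count is thus not particular to the enrichment. The 72 ribosomal protein genes had a median enrichment of 0.29, and 60 of them were above 0, with RPS15A at 1.41 and RPS27 at 1.17. On the beads their medians were -1.05 with miR-491-5p and -1.33 with the control. The 40 replication-dependent histone genes had a median enrichment of 0.49, with H2AC16 at 1.43, while H2AC12 and H2BC7, with pull-down ratios of -5.01 and -2.89, went the other way. The 34 proteasome genes (0.25, PSMD11 at 0.83), 22 DNA replication genes (0.26, MCM4 at 1.12), 24 mitosis genes (0.18, NUSAP1 at 0.74) and 64 nuclear genes of oxidative phosphorylation (0.11) also lay above the random lists. Of the last, 2 were past 2-fold higher and 3 past 2-fold lower, with NDUFB4 at 1.70, NDUFB5 at -1.67 and ATP5ME at -1.65. None of the proteasome or mitosis genes passed 2-fold in enrichment. On the miR-491-5p and control beads the medians lay below 0 for the histone genes (-0.95 and -1.35), the proteasome genes (-0.74 and -0.93), and the oxidative phosphorylation genes (-0.98 and -1.16), each at percentile 0 of the random lists. The DNA replication genes had -0.31, inside the random lists, and -0.57, at percentile 1.53 (2.80, inside, under a stricter match of gene names), and the mitosis genes -0.28 and -0.46, both inside, where all genes had -0.15 and -0.15. The 25 genes of secreted and membrane proteins had 0.27, with FN1 (fibronectin), the only one past 2-fold, at 1.63, LRP1 at 0.92 and CANX at -0.84. In the pull-downs alone their median was 0.13, and in the inputs -0.11. FN1 and CANX owed their values to the inputs, with input ratios of -1.48 and 0.96 and pull-down ratios of 0.14 and 0.13.

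All 13 mRNAs encoded by mitochondrial DNA had an enrichment below 0, with a median of -0.74 at percentile 0.04. ATP6 had -1.40, ND6 -1.30 and CYTB -1.17. The 350 ZNF zinc finger genes had a median of -0.29, with 246 below 0 and 28 past 2-fold lower against 7 higher. In the pull-downs alone their median was -0.15, with 8 lower and 3 higher, and in the inputs it was 0.11. On the beads the median of the ZNF genes was 0.27 with miR-491-5p, with 9 higher and 0 lower. With the control it was 0.51, with 76 higher and 4 lower. Both bead medians lay at percentile 100 of the random lists. As a set the ZNF genes thus stood above the input with both miRNAs, and more so with the control. In enrichment ZNF644 had -1.79, while ZNF384 had 1.99 and ZNF579 1.87. Of 9 small noncoding RNAs, RNY1 had -2.88, RNU4-2 -1.18 and RNU5A-1 -1.13, and the median was -0.62. On the beads the median of these 9 was 0.55 with miR-491-5p, with 2 higher and 3 lower. With the control it was 1.67, with 6 higher and 3 lower. The 17 collagen genes had a median enrichment of 0.42, with COL1A1 at 2.55, COL26A1 at 1.43 and COL6A2 at 1.04. The value of COL1A1 came from the inputs, as its pull-down ratio was 0.01. Of the fixed fibroblast markers only COL1A1, COL1A2 and COL3A1 were measured, with an input median of -1.69 and bead medians of -3.75 and -4.47, each at percentile 0. The collagen list no longer lay outside the random lists in the pull-downs alone, where its median was 0.17. Among the 13 lists inside the random lists were the miRNA machinery (0.16), p53 targets (0.09), endoplasmic reticulum stress (0.06), P-body transcripts (-0.00), interferon response (-0.01), EGFR, RAS and PI3K (-0.04) and cytoplasmic lncRNAs (-0.07).

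**Figure D4:**
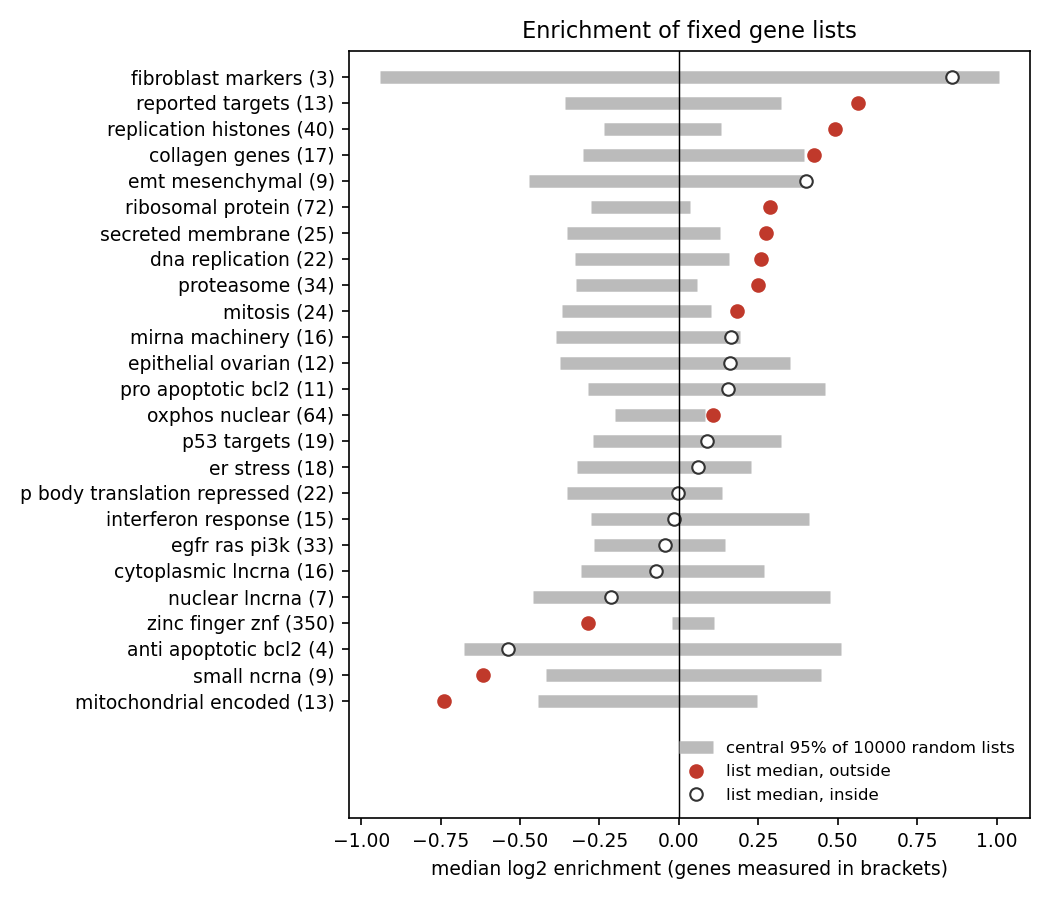
Median log2 enrichment of 25 fixed gene lists (points, with the number of measured genes in brackets) and the central 95% of 10000 random lists matched on expression (grey bars). The reported targets lie above their bar at 0.56 and the mitochondrial mRNAs below theirs at -0.74, and 13 lists lie inside.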

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

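The difference between the transfections was not tested for any gene here, as each group has 1 library. 3 named genes were at least 2-fold higher on the beads with 1 miRNA and at least 2-fold lower with the other, with both counting intervals excluding 0. HP and FGB also had opposite signs of that size, but with few or no counts outside the control input. APOB had a log2 pull-down over input of 2.00 with miR-491-5p and -5.58 with the control, from 2 counts in the input and 14 in the pull-down with miR-491-5p, and 335 and 9 with the control. GPX1P1 had 1.02 with miR-491-5p and -2.58 with the control. H2BC7, a histone gene with near-identical copies, had -1 with miR-491-5p and 2.00 with the control. Over all 12662 genes, 5 were higher with miR-491-5p and lower with the control, and 9 the other way, against 67.7 and 54.1 for independent lists.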

How the results depend on the processing

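The minimum on the pull-down counts, the omission of hepatocyte and fibroblast genes, the stricter name match and the edgeR test were chosen after seeing the data. TMM, pseudocounts of 0.5 and 5, and the fold without the interval left each count of genes within 1.5 times its value, as did the minimum of 50 on the pull-downs and the omission of hepatocyte and fibroblast genes, and, for the enrichment, separate size factors and protein-coding genes only. Total counts gave 888 genes higher and 445 lower for the enrichment, 522 and 263 for the pull-downs, and 577 and 78 on the beads with both miRNAs. They shift the ratios of all genes by 1 factor per comparison, which accounts for the opposite moves. A minimum mean count of 10 gave 1094 and 1137 for the enrichment, 823 and 807 for the pull-downs, 409 and 366 for the inputs, and 1073 higher on the beads. Without a minimum the counts were 1275 and 1302, 1175 and 1199, 479 and 476, and 1129. A minimum of 200 gave 355 higher for the enrichment, 180 higher for the pull-downs, 30 and 23 for the inputs and 123 higher on the beads. These minimums change how many genes enter. A limit of 1.5-fold gave 1677 and 1778 for the enrichment, 1270 and 1349 for the pull-downs, 436 and 384 for the inputs, and 884 and 1708 on the beads. A limit of 4-fold gave 55 and 104, 17 and 48, 1 and 9, and 43 and 6. The pull-downs alone, in place of the enrichment, gave 316 and 402. No value of a named gene or list that had been called changed its sign under the alternatives run for it. Of the values for named genes, 117 under total counts and 9 under TMM moved beyond their counting interval. All 12 lists outside the random lists stayed outside under total counts, a pseudocount of 5 and the stricter name match, and 11 did with a minimum of 200 or in the pull-downs alone, the collagen genes being the exception. The comparison of transcripts with seed sites, and its alternatives, were not run. The edgeR test of pull-down against input, with the transfection as a block, gave 540 genes higher and 662 lower in place of 337 and 360. No paired analysis was possible because of a lack of residual degrees of freedom for the enrichment, and because the pull-downs alone and the inputs alone have 1 library on each side. No library was left out, since each group has 1. Depth limits the named genes of low count, such as TERT, with 18.8 normalised counts in the miR-491-5p input, and MIR491.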

Other observations

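Tests chosen only after their results were seen were those of the expression-matched choice of genes, of the biotin carried by the encoded protein, and of the hepatocyte genes without AMBP and SAA1. When the tests of transcript length and of the Argonaute mRNAs were written, the correlations of all genes with exon length and the median of a list that holds the Argonaute genes had been seen. Genes of the miRNA machinery had unlike values on the beads. The median of the 16 listed was 0.28 with miR-491-5p, at percentile 99.96, and 0.10 with the control, inside the random lists. With miR-491-5p 4 of them were higher and 0 lower, and with the control 6 and 1. TNRC6A had a log2 pull-down over input of 2.17 with miR-491-5p and 3.78 with the control, TNRC6B 2.10 and 4.21, and TNRC6C 1.95 and 3.68, and the name of TNRC6A rests on the looser match of positions, as do those of ISG15 and FGD5-AS1 below. AGO1 had 0.20 and -0.35, AGO2 0.63 and -0.00, AGO3 0.40 and 0.22, and AGO4 0.53 and 1.45. The nuclear lncRNAs, measured although nuclei had been removed, had medians of 1.17 and 1.24 on the beads over 7 genes, with KCNQ1OT1 at 2.07 and 2.07, FTX at 1.81 and 2.18, and MALAT1 at 1.17 and 1.38. NORAD, a cytoplasmic lncRNA chosen after its value was seen, had 1.61 and 3.38, while the fixed list of cytoplasmic lncRNAs had medians of -0.05 and 0.08 over 16 genes, inside the random lists. Of 15 interferon response genes, 1 was lower on the beads with miR-491-5p and 4 with the control, with ISG15 at -1.21 and -1.73. Their median was -0.46 with miR-491-5p, at percentile 1.02, and -0.33 with the control, inside the random lists, while all genes had medians of -0.15 and -0.15.

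Several mRNAs outside the naming rule had both a higher pull-down ratio and a lower input ratio with miR-491-5p, and were chosen after their values were seen. RAVER1 had 1.82 in the pull-downs and -1.18 in the inputs, ERF 1.99 and -0.58, ELOVL1 1.93 and -0.63, and SLC25A23 1.85 and -0.71. TSPAN33 was higher in the pull-downs only, with 2.78 and 0.04. With the control miRNA the pattern was mirrored in YTHDF2, at -2.44 in the pull-downs and 1.01 in the inputs, FGD5-AS1 at -1.97 and 1.32, and SNHG6 at -2.22 and 1.12.

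The pull-down and input ratios come from different libraries. The 316 genes higher in the miR-491-5p pull-down had a median input ratio of -0.09, and 60.8% lay below 0. The 402 genes lower there had a median of 0.13, and 62.7% lay above 0. The difference of 0.221 lay outside the central 95% of random lists matched on expression (-0.04 to 0.06). That comparison was chosen after its result was seen, so it only describes that lists of like expression did not give such a difference. The difference also lay outside the central 95% of lists matched on expression and exon length (-0.03 to 0.06), which argues against transcript length. Lower levels of RNAs bound by each transfected miRNA may account for it, as a hypothesis. No seed sites were tested and the labels give no second pair of libraries, so differences between these libraries stay open.

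The 7 plasma protein genes were found almost only in the control input, and liver RNA in that library was a candidate explanation. Of the summed normalised counts of 19 other hepatocyte genes, 51.3% lay in the control input, between the bounds set beforehand (over 90% for liver RNA, at most 50% against it), so that test did not decide. AMBP and SAA1, with 202 and 254 counts in the miR-491-5p input, held most of the rest, and without them the share was 86.8%, still under that bound, while without APOH, which the stricter name match leaves unnamed, it was 50.8%. Of the 16 with at least 10 counts, 15 were highest in the control input, among them SERPINA1 with 136 counts there and 0 in the miR-491-5p input. Repression by miR-491-5p is argued against by the control pull-down, made from the same lysate: its log2 ratio over the control input for those 19 genes was -2.51 (-2.72 to -2.30), below the 1st percentile of all genes at -1.64. Of other tissue marker sets, the control input held 90.3% of the erythroid set (28 counts) and 85.2% of the plasma cell set (14 counts). It held 28.3% of the muscle set, 16.2% of the brain set and 0% of the pancreas set. The high shares rest on few counts, and partly on HBB and JCHAIN, which the stricter name match leaves unnamed. The low shares are also limited. Of the pancreas set 0 genes reached 10 counts. In the control input TNNT1 held 707 of the 711 muscle counts, and MBP and SNAP25 held 443 and 135 of the 584 brain counts. The shares of these other sets do not decide on liver RNA either.

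ACACA and the TNRC6 mRNAs were grouped because they stood high on the beads with both miRNAs, with a mean log2 value of 3.30 over the 4 genes. Random lists matched on expression and exon length ran from -0.41 to 0.80, and the bound written beforehand counted a value outside them against transcript length, but this comparison cannot decide for genes chosen for their height, so transcript length stays open. The protein made from ACACA carries biotin, and beads could hold it with its mRNA during translation. The other 4 biotin carboxylase mRNAs, ACACB, PC, PCCA and MCCC1, had a median of -0.44 over the means of both transfections, with none of those means above 0.59, so this does not extend to that class. The Argonaute mRNAs had a median of 0.31, so as a set they did not share the TNRC6 values, although AGO4 had 1.45 with the control. What holds the TNRC6 mRNAs stays open.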
